A study of Mus musculus with 2 samples.

How the data were processed

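RNA-seq was carried out on 2 cultures of mouse bone marrow-derived MDSCs, 1 vehicle control and 1 treated with mrWNT2 on day 0 and day 3, both collected on day 6. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with the NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and the GRCm38 (mm10) genome build. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty. The authors deposited a table of raw counts per gene and a table of FPKM (fragments scaled to gene length and library size), each with 1 column per library and 54751 gene rows, 219 of which are gene models without a reference identifier. Column names match the treatment in the labels, and every value column was used.

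The authors' deposited FPKM was checked against the deposited counts. Count, FPKM and gene length together implied 1 library size for each column, and those sizes equalled the totals scaled by DESeq2 median-of-ratios factors: over 10078 genes with more than 50 counts, the log2 ratio from FPKM and that from the counts so scaled differed by at most 1.2e-08. Both tables therefore hold the same libraries, and the FPKM values served only as an alternative. Of the file's gene identifiers, 54495 were found in the reference annotation (GRCm38), 98.3% of them with the same start and end. Coordinates are those of the deposited table, 1-based.

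Counts were scaled with TMM factors (0.992 for control, 1.01 for mrWNT2) in edgeR 4.0.16 under R 4.3.3, and expressed as CPM, the count scaled to the TMM-adjusted library size. With 1 library per group no test could be run and no p-value is given. Each gene's log2 ratio of mrWNT2 over control was computed without a pseudocount, with an exact 95% binomial (Clopper-Pearson) interval from the 2 counts. A count of 0 was replaced by 3 counts, about its 1-sided upper 95% limit, and no ratio was given where 0 stood against 3 or fewer. The control library held 13474453 counts and the mrWNT2 library 12621110, so at that limit 0 counts corresponds to 0.224 and 0.236 CPM. Intervals and floors cover counting error only. Reads carry no molecular identifiers, so amplified copies count as separate reads and the intervals may be too narrow even for counting error. Genes with a mean of at least 1 CPM over the 2 libraries were kept (12856), and those with a log2 ratio of at least 1 in size were counted.

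The 38 gene lists were written before the data were examined. They covered WNT targets and pathway components, MDSC suppressive genes, primary and secondary or tertiary granules, mature neutrophils, monocytes, macrophages, dendritic cells, MHC class I and class II, interferon-stimulated, NF-kB and inflammatory, chemokine and alternative activation genes. Others covered G1/S, G2/M, glycolysis, hypoxia, oxidative phosphorylation, mitochondrially encoded, cholesterol, lipid, endoplasmic reticulum stress, antioxidant, ribosomal protein, immediate early and apoptosis genes. Marker lists covered B cells, T, NK and innate lymphoid cells, basophils and mast cells, eosinophils, erythroid cells, megakaryocytes, stem and progenitor cells, stroma and endothelium, osteoclasts and sex-linked genes. Of 823 listed symbols, 2 (Azu1 and Bim) were not found. For each list the median log2 ratio of its measured members was placed among the medians of 10000 random lists, made by replacing each member with a gene from the same of 20 expression bins, drawn with replacement. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5. The counting interval of a median came from 1000 binomial resamples of its members' counts. Members were described as at least 1.5-fold higher, at least 1.5-fold lower or between.

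Genes named were the 12 highest and 12 lowest ratios among protein-coding genes with a mean of at least 10 CPM (without Gm and Rik models), and the 6 largest gains and 6 largest losses in CPM. They also included up to 4 members with the largest ratio of each list that stood apart, a preset group of WNT, suppressive and myeloid genes, and the sex-linked genes. Other list members are named as examples, chosen after their values were seen.

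The method was tested on simulated counts for this comparison with 12862 genes. There, 95.3% of intervals held the simulated ratio, 28 of 12639 unchanged genes came out at least 2-fold higher and 31 at least 2-fold lower by counting error alone, and 100% of 3-fold and 98.9% of 4-fold changed genes were called. A list of 30 genes changed by 1.5-fold came out at a median of 0.59 and percentile 100, and an unchanged one at percentile 63.7. Simulated counts varied independently and by counting error alone, and 1 unchanged list was drawn. The simulation therefore does not show how often lists of genes regulated together would stand apart between cultures treated alike.

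Alternatives fixed before the data were examined were library totals, DESeq2 size factors (DESeq2 1.42.0) and upper-quartile factors, minimums of 5 CPM, 10 CPM and none, thresholds of 1.5-fold and 3-fold, an interval wholly beyond 2-fold, protein-coding genes alone, and FPKM with pseudocounts of 0.1 and 1. The suppressive list without NF-kB members was added afterwards.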

Results

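The data set held 2 RNA-seq libraries of myeloid-derived suppressor cells (MDSCs), immature myeloid cells named for their capacity to dampen T cell responses, that had been grown from mouse bone marrow. The control library came from vehicle-treated cells and the other from cells given mrWNT2. WNT2 is a secreted ligand of the WNT signalling pathway. Per the labels, treatment was given on day 0 and day 3 and cells were taken on day 6. Each group had 1 library, with 13474453 counts for control and 12621110 for mrWNT2, and 20574 and 20202 genes had at least 1 count. The most abundant transcript in both was Chil3, which took 5.04% of control and 4.25% of mrWNT2 counts, and the log2 levels of the 2 libraries correlated across genes with r = 0.979 (genes are not independent replicates).

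The comparison asked how exposure to WNT2 during differentiation alters gene expression in these cells, which the series' title links to colorectal cancer. In the mrWNT2 library, 20 of 27 measured NF-kB and inflammatory genes were at least 1.5-fold higher, among them Il1a (19.9-fold), Csf3 (30.3-fold) and Il1b (5.91-fold). Chemokine genes went both ways, with Cxcl1 7.16-fold higher and Ccl8 16.4-fold lower. Macrophage genes were mostly lower, among them Cd5l (18.6-fold), Retnla (12.5-fold) and the mannose receptor gene Mrc1 (3.07-fold). Of 32 measured genes of suppressive function, 8 were at least 1.5-fold higher, among them Nos2 (6.47-fold), and 1 was lower, Arg1 (2.70-fold). Genes that canonical WNT signalling is known to induce were not higher as a group, and 14 of the 22 listed were too weakly expressed to be measured. There were no replicates, so none of these differences has a replicate check, and every interval covers counting error only and compares the 2 libraries, not the conditions. The interval of a gene's fold is a 95% binomial (Clopper-Pearson) interval, and that of a list's median comes from resampled counts.

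Of 12856 genes with a mean of at least 1 CPM (counts scaled to library size), 435 were at least 2-fold higher in the mrWNT2 library, 423 of them with an interval above a ratio of 1. Another 320 were at least 2-fold lower, 305 of them with an interval below 1. Protein-coding genes made up 377 of the higher and 214 of the lower genes. Most genes differed little: 85.4% lay within 1.5-fold, and the 5th and 95th percentiles of the log2 ratio were -0.71 and 0.78. Among the 8543 genes with a mean of at least 10 CPM, 154 were at least 2-fold higher and 61 at least 2-fold lower.

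**Figure D1:**
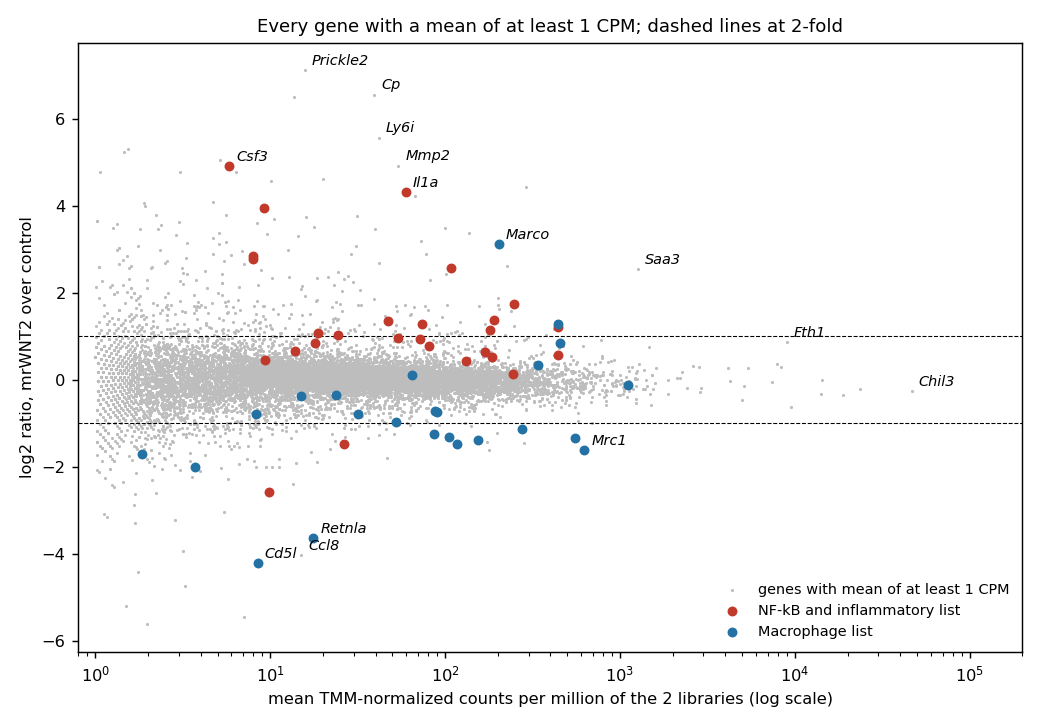
Log2 ratio of mrWNT2 over control against the mean level of each gene in TMM-normalized CPM (log axis), with 1 grey point per gene with a mean of at least 1 CPM, and the members of the NF-kB and macrophage lists in red and blue. Of the measured NF-kB list genes, 20 of 27 were at least 1.5-fold higher, and of the measured macrophage list genes 16 of 24 were at least 1.5-fold lower.

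Among protein-coding genes with a mean of at least 10 CPM, the highest ratio was that of Prickle2 (ENSMUSG00000030020, chromosome 6, 92370908 to 92706155, GRCm38), which encodes a planar cell polarity protein. It had 3 counts in control and 397 in mrWNT2, a 139-fold ratio (interval 47.3 to 678). Ceruloplasmin, the copper-carrying ferroxidase encoded by Cp (chromosome 3, 19957054 to 20009145), was 94.5-fold higher (52.6 to 190). The potassium channel gene Kcnj15 was 90.4-fold higher (35.0 to 334), Ly6i 47.5-fold (31.5 to 75.2), and the gelatinase gene Mmp2 30.3-fold (22.6 to 41.6). The transcription factor gene Pou2f2 was 24.5-fold higher, the metalloreductase gene Steap4 23.7-fold, Il1a 19.9-fold and the endogenous retroviral gene Erv3 18.8-fold. Ptgfrn, Serpina3f and Fstl1 were 13.7-fold, 13.4-fold and 13.1-fold higher. At the other end, the chemokine gene Ccl8 (chromosome 11, 82115185 to 82116799) was 16.4-fold lower (10.7 to 26.5), with 380 counts in control and 22 in mrWNT2. Retnla, a marker of alternatively activated macrophages, was 12.5-fold lower (8.79 to 18.4), and Svep1 was 5.24-fold lower. Ifit1bl2, Mpzl2, Cacna1d, Fbp1 and Emp1 were between 3.49-fold and 3.99-fold lower, and Mrc1, Retnlg, Ccl2 and Fabp5 between 2.76-fold and 3.07-fold lower. The largest gain in level was that of the ferritin heavy chain gene Fth1, from 6356 to 11607 CPM. It was followed by Thbs1 (1.28-fold higher), by the acute-phase gene Saa3 (372 to 2164 CPM, 5.82-fold higher), and by Lcn2, Lyz2 and Psap, the last of which was 1.2-fold higher. The largest losses were in Chil3 (50762 to 42219 CPM, 1.2-fold lower), Ngp, the lactoferrin gene Ltf (1.55-fold lower), S100a9, S100a8 and Ccl6. Ly6i, Serpina3f, Ifit1bl2, Erv3, the Ccl2, Ccl7, Ccl8 and Ccl12 cluster, the Ear and MHC genes and Fth1 have close relatives or processed copies in the genome, so the split of their reads is uncertain.

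The NF-kB and inflammatory list had the highest median of the 38 gene lists over members with a mean of at least 1 CPM (over those with at least 10 CPM, its 0.96 was second to 1.005 for T, NK and innate lymphoid genes). Of its 30 genes, 27 were measured: 20 were at least 1.5-fold higher, 2 at least 1.5-fold lower and 5 between. The list's median log2 ratio was 1.03 (counting interval 0.92 to 1.16), at percentile 100 of 10000 random lists matched on expression. Csf3, which encodes the granulocyte growth factor G-CSF, had 5 counts in control and 144 in mrWNT2 (30.3-fold, interval 12.7 to 94.7). Il1a (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972) had 76 and 1440 counts (19.9-fold, 15.8 to 25.4). Ccl5 was 15.5-fold higher (9.19 to 28.2) and the neutrophil chemoattractant gene Cxcl1 7.16-fold (4.73 to 11.3). Tnfaip3, which encodes a feedback inhibitor of the pathway, was 3.33-fold higher (3.14 to 3.53), and the inhibitor gene Nfkbia was 1.49-fold higher (1.43 to 1.54). The members that were lower were the monocyte chemoattractant genes Ccl2 (2.79-fold) and Ccl7 (6.0-fold). Chemokines and their receptors went both ways: of 25 measured genes, 11 were at least 1.5-fold higher and 8 at least 1.5-fold lower. Ccl5, Cxcl1 and Ccl22 (5.02-fold) were among the higher genes, and Ccl8 and Ccl12 (8.18-fold) among the lower. The median of that list was 0.34 (-0.09 to 0.65) at percentile 99.99, and 0.57, at percentile 100, over the 17 members with a mean of at least 10 CPM. However, it was -0.31, at percentile 0, when no expression minimum was set. The interferon-stimulated list did not stand apart (median 0.12, 0.00 to 0.25, percentile 89.8), with 5 of 30 members at least 1.5-fold higher and 3 lower. Without an expression minimum its percentile was 99.5, and over members with a mean of at least 10 CPM it was 44.3 (median 0.03).

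Of 34 genes tied to MDSC suppressive function, 32 were measured, and 8 of them were at least 1.5-fold higher, 1 lower and 23 between. The list's median was 0.10 (0.06 to 0.16) at percentile 99.4, and its mean was 0.46. Without the members shared with the NF-kB list, an alternative chosen after the values were seen, the median of the remaining 30 genes was 0.07 at percentile 96.4, inside the range of the random lists. Ptges, which encodes a prostaglandin E synthase, was 9.12-fold higher (7.85 to 10.6). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), which encodes inducible nitric oxide synthase, was 6.47-fold higher (5.44 to 7.75). The arginine transporter gene Slc7a2 was 6.18-fold higher (5.74 to 6.65), and Il1b 5.91-fold (5.33 to 6.58). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which encodes the arginine-degrading enzyme arginase 1, was 2.70-fold lower (2.53 to 2.89), at 252 CPM in control and 93.3 in mrWNT2. Il10 was 2.80-fold higher (1.52 to 5.46) from 15 and 40 counts. Cybb, which encodes a subunit of the phagocyte NADPH oxidase, was 1.21-fold higher, and Cd274, which encodes PD-L1, was 1.18-fold higher (1.09 to 1.27). S100a8 and S100a9 were 1.25-fold and 1.15-fold lower. The intervals of Tgfb1 and Stat3 included a ratio of 1.

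**Figure D2:**
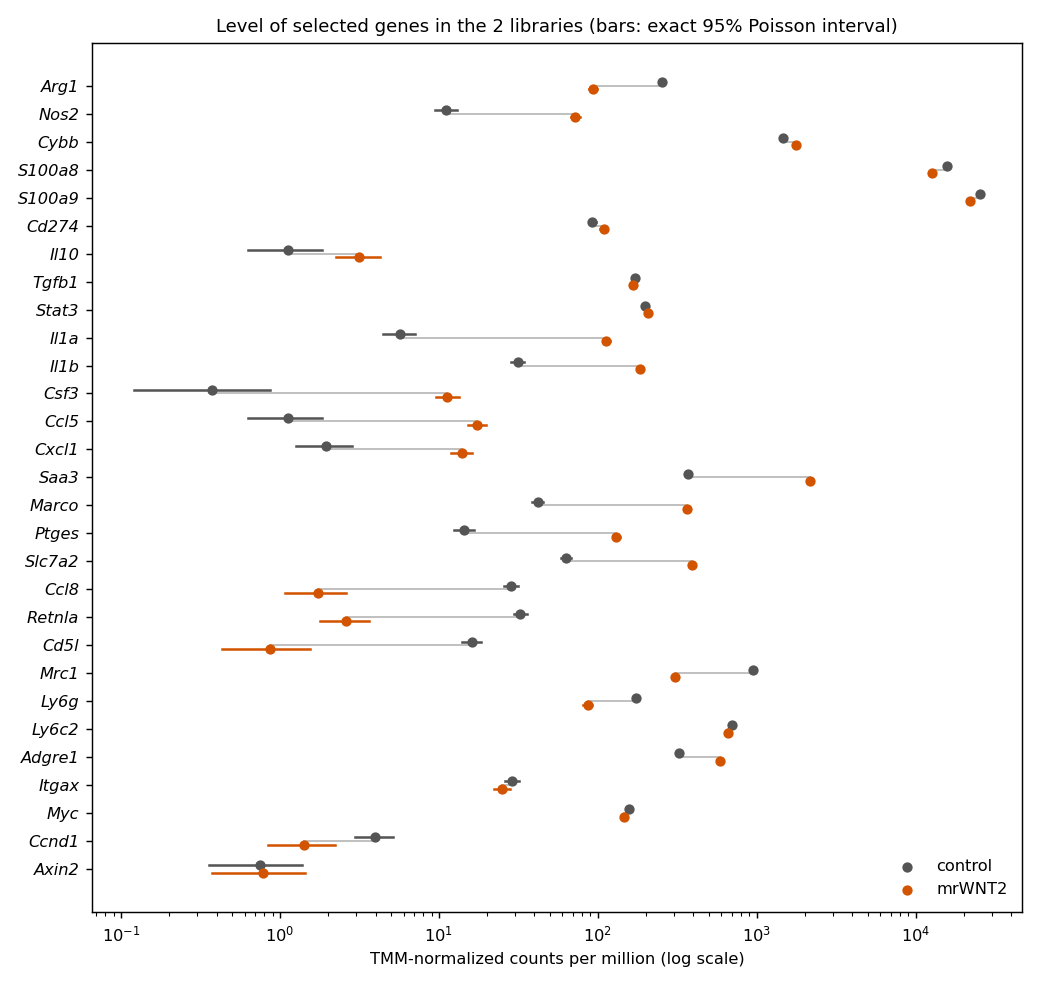
TMM-normalized CPM (log axis) of genes of suppressive, inflammatory, myeloid and WNT function in the control (grey) and mrWNT2 (orange) libraries, with exact 95% Poisson intervals of each count as bars. Nos2 was 6.47-fold higher and Il1a 19.9-fold higher in mrWNT2, Arg1 was 2.70-fold lower, and Axin2 had 10 counts in each library.

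Macrophage genes were mostly lower in the mrWNT2 library. Of 24 measured genes, 16 were at least 1.5-fold lower, 3 at least 1.5-fold higher and 5 between, and the median log2 ratio was -0.88 (-1.08 to -0.80) at percentile 0. Cd5l was 18.6-fold lower (10.2 to 37.8), Retnla 12.5-fold, and the complement receptor gene Vsig4 4.0-fold (2.40 to 6.99). Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) was 3.07-fold lower (2.96 to 3.19), at 943 CPM in control and 307 in mrWNT2. The complement gene C1qb, the apolipoprotein gene Apoe and the haemoglobin scavenger receptor gene Cd163 were 2.5-fold, 2.55-fold and 2.61-fold lower. In the opposite direction, the scavenger receptor gene Marco was 8.67-fold higher (7.94 to 9.48), Lpl 2.45-fold, and Adgre1, which encodes F4/80, 1.8-fold (1.73 to 1.86). The overlapping list of alternative activation genes had a median of -0.20 (-0.28 to -0.11) at percentile 0.20, with 7 of 20 members at least 1.5-fold lower and 5 higher. Clec7a was 3.04-fold lower beside Retnla and Mrc1, and Ccl22 was 5.02-fold higher. Genes of MHC class II presentation and costimulation had a median of -0.28 (-0.40 to -0.11) at percentile 0.15, with 4 of 14 members at least 1.5-fold lower and 2 higher. Cd74, the class II invariant chain gene, was 1.95-fold lower and Ciita 2.43-fold lower. In contrast, H2-Oa was 3.18-fold higher, and H2-Ob 4.38-fold higher (1.75 to 13.1) from 6 and 25 counts. That list's percentile was 9.33 without an expression minimum, inside the random range. MHC class I genes had a median of 0.20 (0.11 to 0.26) at percentile 99.4, with H2-K1 and Psmb8 1.41-fold and 1.47-fold higher, and 1 of 15 members, H2-Q7, at least 1.5-fold higher with an interval that included 1.

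Granulocyte genes were split by granule class. Secondary and tertiary granule genes, which are made at later stages of neutrophil maturation, had a median of -0.38 (-0.42 to -0.35) at percentile 0, with 5 of 18 at least 1.5-fold lower and 1 higher. Ly6g, the mouse granulocyte surface marker, was 2.0-fold lower (1.87 to 2.16), Mmp9 1.98-fold (1.92 to 2.05) and Ifitm6 1.63-fold, while the haptoglobin gene Hp was 1.70-fold higher (1.67 to 1.74). All 10 measured primary granule genes were within 1.5-fold (median -0.02, -0.06 to 0.06, percentile 45.6; mean 0.00). Mature neutrophil genes did not stand apart (median -0.04, -0.08 to 0.01, percentile 44.5): 2 of 22 were at least 1.5-fold higher, Fpr1 and Cxcl2, and 2 lower, Retnlg at 3.06-fold and Mmp25 at 1.5-fold. The monocyte list did not stand apart either (median -0.07, -0.22 to -0.03, percentile 16.4; mean 0.02). Its marker Ly6c2 was 1.06-fold lower (1.02 to 1.09), and 3 of its 16 measured members were at least 1.5-fold higher, namely Csf1r (2.37-fold), Cd14 (2.03-fold) and Fn1 (1.71-fold). Dendritic cell genes had a median of 0.07 (-0.10 to 0.54) at percentile 68.9, with 6 of 14 at least 1.5-fold higher and 2 lower. Over the 9 members with a mean of at least 10 CPM that median was 0.75, at percentile 100. Itgax, which encodes CD11c, was 1.15-fold lower with an interval of 0.99 to 1.34.

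Most canonical WNT target genes were barely expressed in either library. Axin2 had 10 counts in each (1.05-fold, with a ratio between 0.39 and 2.82), Tcf7 had 3 and 6, and Lef1 had 1 and 0. Wnt2 itself had 0 counts in both libraries, which allows up to 0.224 CPM in control and 0.236 CPM in mrWNT2. Of 22 listed targets, 8 were measured, 0 of them at least 1.5-fold higher and 1 lower. The interval lay below a ratio of 1 for 4 of the 8 and above it for 0, and their median was -0.15 (-0.35 to -0.00) at percentile 18.0. The lower gene was Ccnd1, which encodes cyclin D1, with 53 and 18 counts (2.80-fold, 1.61 to 5.08). Myc was 1.07-fold lower (1.01 to 1.14). Components of the pathway, such as receptors and transducers, had a median of -0.15 (-0.19 to -0.06) at percentile 0.39, though 20 of 22 were within 1.5-fold. The receptor gene Fzd1 was 1.75-fold higher (1.21 to 2.56), and Ctnnbip1 and Dvl1 were 1.64-fold and 1.41-fold lower. Fzd5 was 1.43-fold lower with an interval that included 1. Without an expression minimum the components' percentile was 22.3, inside the random range.

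Genes of growth and energy metabolism were slightly higher in the mrWNT2 library. All 44 measured ribosomal protein genes were within 1.5-fold, with a median of 0.19 (0.17 to 0.21) at percentile 100 and Rpl3 1.30-fold higher. All 37 oxidative phosphorylation genes were within 1.5-fold too (median 0.22, 0.18 to 0.26, percentile 100), with Uqcrfs1 1.36-fold and Cycs 1.35-fold higher. Glycolysis genes had a median of 0.21 (0.17 to 0.25) at percentile 100. Aldoc was 1.97-fold higher, Pfkfb3 1.85-fold and Tpi1 1.55-fold, and the glucose transporter gene Slc2a3 was 1.72-fold lower. Hypoxia response genes had a median of 0.24 (0.15 to 0.33) at percentile 99.96, with Bnip3 1.58-fold higher. P4ha2 was 2.32-fold lower (1.03 to 5.73), from 22 and 9 counts. Endoplasmic reticulum stress genes had a median of 0.25 (0.17 to 0.28) at percentile 99.97, with the chaperone gene Hspa5 1.42-fold higher and Chac1 1.47-fold lower. The cell cycle lists were also above the random range. G1/S genes had a median of 0.18 (0.13 to 0.22) at percentile 99.9, with 1 of 29, Fen1, at least 1.5-fold higher. G2/M genes had a median of 0.16 (0.08 to 0.16) at percentile 99.91, with all 30 within 1.5-fold. Mitochondrially encoded genes (median 0.12, percentile 94.9) did not stand apart, but did without an expression minimum (percentile 99.4). Cholesterol synthesis (median -0.05, percentile 13.7), lipid uptake and oxidation (0.06, 83.4), antioxidant (0.01, 66.9), immediate early (0.01, 54.1) and apoptosis regulator genes (0.08, 87.5) did not stand apart. Antioxidant members included Sod2, a mitochondrial superoxide dismutase gene, which was 3.71-fold higher (3.47 to 3.97).

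**Figure D3:**
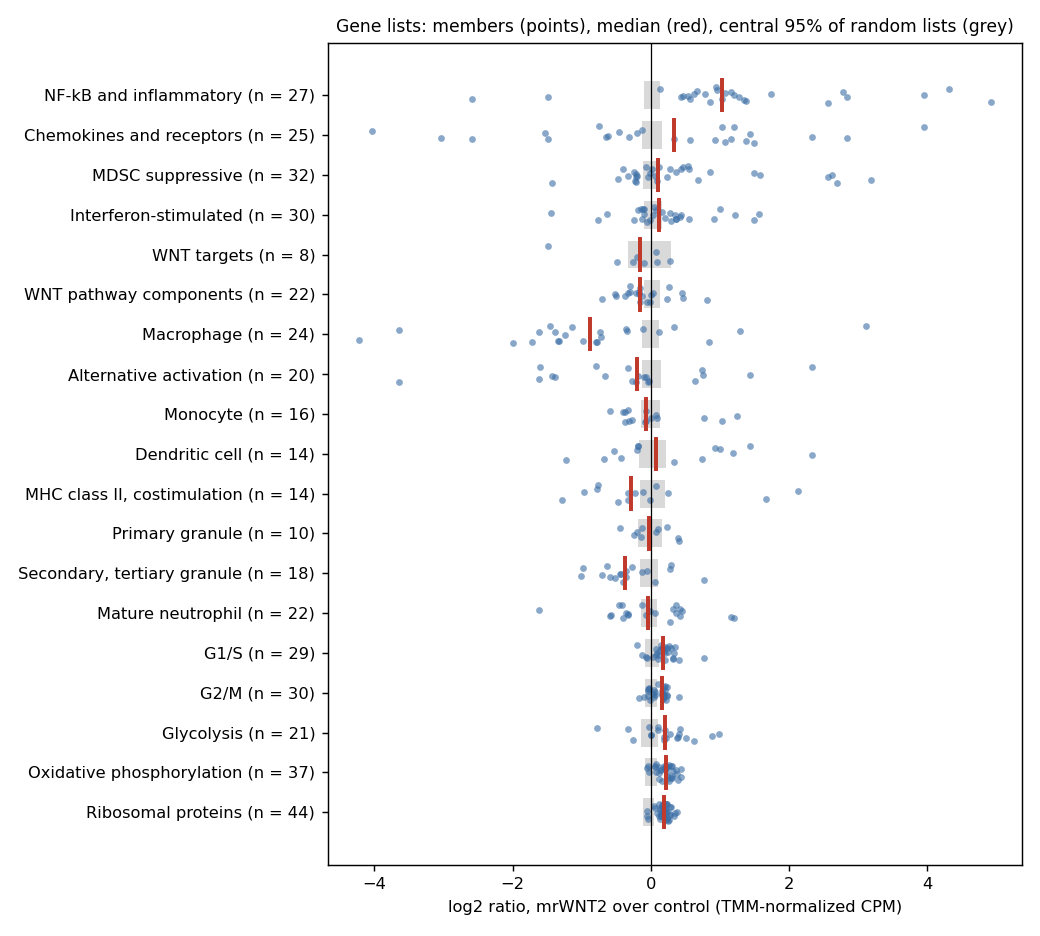
Log2 ratio (mrWNT2 over control, TMM-normalized CPM) of the measured members of 19 of the 38 gene lists (points, scattered vertically for legibility), with each list's median in red and the central 95% of 10000 expression-matched random lists in grey. The NF-kB list's median was 1.03 and the macrophage list's was -0.88.

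Markers of other cell types were followed as a measure of culture composition. Stromal and endothelial genes had a median of -0.98 (-1.22 to -0.73) at percentile 0 over 9 measured genes. Col1a2, Sparc and Bgn were 4.18-fold, 3.07-fold and 2.96-fold lower, each from under 70 control counts, while the leptin receptor gene Lepr was 7.94-fold higher (5.65 to 11.5). Over the 3 of these genes with a mean of at least 10 CPM the median was 0.20. Eosinophil genes had a median of -0.24 (-0.41 to -0.08) at percentile 1.34, with Ear2 1.48-fold and Alox15 1.74-fold lower, although the eosinophil granule gene Epx was 1.32-fold higher. The T, NK and innate lymphoid list had 5 of 18 genes measured, with a median of 0.43 (0.21 to 0.67) at percentile 99.0, and of 1.005 over the 4 with a mean of at least 10 CPM. Of the 5, 2 were at least 1.5-fold higher, 1 lower and 2 between. Thy1 was 7.48-fold higher (6.0 to 9.4), Il2ra 2.98-fold (2.5 to 3.57) and Il7r 1.35-fold (1.15 to 1.58). Gzmb, with 26 and 14 counts, was 1.77-fold lower with an interval that included 1. Cd3d, a T cell receptor complex gene looked up after these values were seen, had 14 counts in control and 9 in mrWNT2. Lists for B cells (median -0.39, percentile 9.96), basophils and mast cells (0.04, 63.0; mean -0.14), erythroid cells (-0.19, 20.4), megakaryocytes (-0.12, 12.5), stem and progenitor cells (-0.12, 9.09; mean 0.09) and osteoclasts (0.09, 78.2) did not stand apart. Xist had 0 counts in both libraries, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were within 1.12-fold (sex-linked list median -0.13, percentile 10.5), so the cultures showed the same sex-linked pattern.

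In all, 19 of the 38 lists stood apart, 12 above and 7 below the random range. By chance 1.9 would be placed outside it if the genes within a list varied independently, which cannot be assumed. Genes of a list share regulation, so a percentile describes these libraries and does not stand in for replicate cultures. Stroma no longer stood apart at 10 CPM, nor WNT components and MHC class II without a minimum, where chemokines moved to percentile 0. Dendritic genes stood apart only at 10 CPM, and interferon-stimulated and mitochondrially encoded genes only without a minimum. Lists also shared measured members with others: 16 of 20 for alternative activation, 16 of 25 for chemokines and 11 of 27 for NF-kB.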

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

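The suppressive list without NF-kB members was the alternative chosen after the data were seen, with a median of 0.07. Counts of genes at least 2-fold higher and lower (435 and 320) depended most on the expression minimum and threshold: 220 and 109 at 5 CPM, 154 and 61 at 10 CPM, 1543 and 1270 with no minimum, 980 and 902 at 1.5-fold, 198 and 81 at 3-fold, 201 and 70 with the interval wholly beyond 2-fold, and 171 and 73 from FPKM with a pseudocount of 1, which shrinks ratios of low genes. The other 10 recomputed counts stayed within 1.5 times, and the higher share of 57.6% was 60.1%, 54.5% and 53.4% under library totals, DESeq2 and upper-quartile factors. Those scalings shifted every ratio by 0.02, -0.03 and -0.05 on the log2 scale. The suppressive list's median was 0.053 under upper-quartile factors. The macrophage median was -0.76 at 10 CPM and -0.71 from FPKM with a pseudocount of 1, where the NF-kB median was 0.89. Of 265 recomputed list medians 232 stayed within the counting interval, 31 lay outside it, and 2 of lists that stood apart reversed: stroma and endothelium at 10 CPM (0.20, over 3 genes), and chemokines without a minimum (-0.31), which adds members with few counts. Medians of 6 lists that did not stand apart also changed sign, 13 times in all, among them B cells (0.07) and dendritic cells (-0.08) without a minimum and mitochondrially encoded genes (-0.01) under upper-quartile factors. Of 53 named genes at least 2-fold apart, 52 stayed so under every scaling, 50 from FPKM with a pseudocount of 0.1 and 43 with a pseudocount of 1, where the log2 ratio of Tcf7, with 3 and 6 counts, was 0.12. Depth limits the WNT targets under 1 CPM: counting error alone left the Axin2 ratio anywhere from 0.39 to 2.82.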

Other observations

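The genes looked up here, and the tests on cell type shares, endotoxin and WNT targets, were chosen after the results were seen. Acod1, which encodes the enzyme that makes itaconate, was 11.2-fold higher in the mrWNT2 library (interval 9.79 to 13). Ass1, which encodes the first enzyme of the route that rebuilds arginine from citrulline, was 11.1-fold higher (8.89 to 13.9). The next enzyme of that route, Asl, was 1.04-fold lower with an interval that included 1. These stood beside the higher Nos2 and Slc7a2 and the lower Arg1. Of genes tied to iron, Cp, Steap4 and Fth1, already named above for their large ratios or gains, were 94.5-fold, 23.7-fold and 1.83-fold higher. Among other genes with a role in iron transport or storage that were looked up, Slc11a1 was 1.72-fold higher (1.61 to 1.84). The exporter gene Slc40a1 was 1.73-fold lower (1.61 to 1.86). Ftl1 and Tfrc were both 1.06-fold lower, the intervals of Trf and Slc39a14 included a ratio of 1, and Hamp had 0 and 3 counts. The basement membrane collagen genes Col4a1 and Col4a2, which lie head to head on chromosome 8, were 8.39-fold and 4.19-fold higher, unlike the fibrillar collagen gene Col1a2. Of the planar cell polarity genes related to Prickle2, Prickle3 was 1.25-fold lower (1.09 to 1.44) and the intervals of Prickle1, Vangl2 and Celsr1 included a ratio of 1.

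A gene model with no reference name, on the minus strand of chromosome 13 from 55184447 to 55189172, had 343 counts in control and 7089 in mrWNT2, 21.7-fold higher (19.5 to 24.3). Its annotation in the deposited table is a match to a retroviral Pol polyprotein. It lies 15687 bases from Fgfr4, which had 0 counts in both libraries, and 20609 bases from Nsd1, which was 1.03-fold lower, and a plus-strand model over the same interval had 0 counts. Of 39 such retroelement models with at least 1 CPM, 4 were at least 2-fold higher and 6 at least 2-fold lower, with a median log2 ratio of -0.39. Reads from repeated elements can align to several copies, so the locus is uncertain.

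For the higher NF-kB and inflammatory genes, a bias by GC content or gene length is argued against by the small size of that trend across genes (SD 0.022 on the log2 scale), so that its removal moved little and left a median log2 ratio of 0.99. Counting error of low genes is argued against by the median over members with a mean of at least 10 CPM, which was 0.96. A larger share of 1 listed cell type stays open: medians for T, NK and innate lymphoid cells (0.43, 0.21 to 0.67) and dendritic cells (0.07, -0.10 to 0.54) lay below the NF-kB interval from 0.92, but over members with a mean of at least 10 CPM they were 1.005 from 4 genes and 0.75 from 9, although the T cell genes Cd3e (1 and 0 counts) and Trac (1 and 2) were near absent. Endotoxin carried in with the mrWNT2 preparation could raise the same genes and stays open: the interferon-stimulated list, which the endotoxin receptor also induces, had a median of 0.12 that neither stood apart nor lay below 0. A response to WNT2 itself stays open, since the treatment and its preparation came together in 1 library.

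For the lower macrophage genes the same small trend argues against GC content or gene length as the cause, and its removal left a median of -0.94. A smaller share of macrophages and monocytes, with no change within them, would lower together the markers that only these cells express. Of the 40 measured members of the macrophage and monocyte lists, 27 had an interval below a ratio of 1 and 8 above it. Those above were Marco, Lpl, Csf1r, Cd14, Adgre1, Fn1, Cd68 and Cd300lf. In the macrophage list alone, 19 of 24 lay below and 4 above. Each library pooled all cells of a culture, so the higher members may have risen in other cells. A smaller share therefore stays open, and a changed state of these cells, fewer of them, or both may account for the pattern. With 1 culture per group, variation between cultures was not tested.

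Of the 8 measured canonical WNT targets, 0 had an interval above a ratio of 1 under any of the scalings, and at least 3 had one below it under each. These targets were thus not higher as a group in this mrWNT2 library on day 6. The counts restate the values that prompted the question, so they describe the pattern and do not check it. For Axin2 and the other targets under the expression minimum, a rise stays open, since 10 Axin2 counts per library allow a ratio of up to 2.82. An earlier response that had ended by day 6, or signalling outside the canonical route, was not tested.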
